A study of Homo sapiens with 32 samples.

How the data were processed

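The series holds bulk RNA sequencing of CD4+ T cells isolated from children's blood, as 32 libraries in 3 labelled groups: healthy (10), active JIA on treatment (12) and JIA in clinical remission on medication (10). The labels describe a positive selection but name a kit sold for enrichment, and part of their library text appears to belong to a DNA assay, so how the cells were selected, and with that which other cells were left, is uncertain. Per the submitters' processing notes, reads were aligned with Bowtie2 to build hg19, handled with SAMtools and counted with HTSeq, with no versions given. The deposited files give 1 raw read count per gene and library, in whole numbers with no normalisation by the authors, and end in 5 HTSeq summary lines. The annotation release, strand setting and mapping-quality cut-off are not given in the sources used here. The summary lines were left out of library sizes and tests and were used as measures of mapping. Of all tallied reads, 41% were assigned to genes in healthy, 33.2% in active and 41.3% in remission libraries, and 27.4%, 39.4% and 28% were set aside for low mapping quality. Not aligned were 15.3%, 11.5% and 15.1%, without a feature 13.2%, 13.2% and 12.2%, and ambiguous 3.24%, 2.63% and 3.31%.

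Gene identifiers were matched by Ensembl number to a reference annotation (GENCODE 44), which named 51996 of them. It is on GRCh38 while the files use hg19, so no coordinates are printed. Of the rows, 16545 held 0 in every library. Groups were taken from the labels, and replicates were numbered in the order of deposit, which pairs nothing. The labels name no batch and do not say whether every library comes from a different child, so p values measure the spread between these libraries. No 2 libraries of a group were duplicates of each other: the lowest chi-square per gene between any 2 was 16.1 in healthy (45 pairs), 19.6 in active (66 pairs) and 4.68 in remission (45 pairs).

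The group comparisons, main tests, 38 gene lists, rule for named genes and the first set of other settings were fixed before the data were examined. Counts were fitted in edgeR 4.0.16 (R 4.3.3) with 1 negative binomial model over all 32 libraries, TMM scaling, filterByExpr by group (minimum count 10, minimum total 15), robust quasi-likelihood F tests and Benjamini-Hochberg adjustment over 19798 genes at 0.05. Positive log2 fold changes mean higher in the first group named, and CPM are normalised with TMM. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry, which asks only whether a list's genes move 1 way. Of the list entries 14 found no row in the files. Means of log2 CPM (prior count 2) over markers and mapping measures were compared by two-sided permutation tests with 100000 permutations, adjusted by Benjamini-Hochberg over 36 marker tests or 24 mapping tests. Marker tests under other settings used 20000 permutations. Spread within a group was compared as each library's mean absolute deviation from its group's median profile.

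Named genes were, per comparison, the 10 higher and 10 lower with the smallest p among genes that passed, had a symbol, a mean CPM of 1 or more and the same direction in group medians, and up to 4 passing members of each list. With fewer than 5 passing genes the 10 with the smallest p were named as not passing, and lists without a passing member could give 2 members. Y-linked genes, XIST, TSIX and receptor segments were never named. Chosen after their values were seen, to name members behind small counts, were TBX21, HAVCR2, CXCR3, IKZF2, FOXP3, IL2RA, LCK, LAT, NFATC1, CIITA, TAPBP, IRF1, TIMMDC1, STAT3 and IL2RG.

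The tests were tested on simulated data made from these libraries, with 200 changed genes per comparison. In the comparison of active with healthy, edgeR recovered 44.8%, 65.7% and 87.9% of genes changed 1.5-, 2- and 4-fold, with 10 false calls. The values were 41.8%, 53.7% and 84.8% with 3 false calls for remission against healthy, and 46.3%, 58.2% and 80.3% with 5 false calls for active against remission. Camera found the 1 changed list in each, with 0 false calls, and 10 simulations without any change gave 0 calls at most. Each gene was drawn independently there, so these simulations cannot show how camera behaves where members of a list move together. In the real data the estimated correlation reached 0.88 in the monocyte marker list. In a simulated trend with gene properties 160 false calls were made without the offsets described next and 4 with them, at 63.5% and 61% recovery. That trend was made with the same spline fit as the offsets, so it does not show how they act on a trend of another form.

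The settings changed 1 at a time were DESeq2-type size factors, library size alone, no filter, CPM of 1 or more in 10 libraries, edgeR without robust fitting, 13 surrogate variables (sva 3.50.0), a monocyte and neutrophil covariate, a covariate from sex-linked transcripts, thinning to the smallest library, only the 2 groups compared, DESeq2 1.42.0, voom with quality weights, and leaving out each library. Added after seeing the data were per-library spline offsets (4 knots per property) for exon length, GC content and mean exon size (known for 96.4% of tested genes), a covariate of low-mapping-quality reads per gene count, covariates from NK or monocyte markers, coding genes with no processed pseudogene named after them, and leaving out the 5 shallow libraries. For each comparison 60 splits of the libraries, the real one included, were fitted. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and tables with pandas 2.3.3. Splicing, variants and immune receptor sequences were left out, since gene counts do not hold them. Values of some single genes that the rule names are not reported here.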

Results

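RNA was sequenced from CD4+ T cells of children's blood. The labels give 3 groups: healthy controls (n = 10), juvenile idiopathic arthritis (JIA, a chronic joint inflammation that begins in childhood) that was active under treatment (n = 12), and JIA in clinical remission on medication (n = 10). Each of the 32 libraries gave a read count per annotated gene, and 19798 genes had enough counts to be tested. Gene counts per library, in replicate order and in M (mega), were 21.86, 21.71, 22.01, 20.65, 19.35, 21.97, 27.37, 21.56, 18.4 and 30.18 in the healthy group. They were 27.65, 3.63, 31.75, 28.71, 24.54, 22.23, 22.11, 24.23, 19.09, 18.66, 21.55 and 22.83 in the active group, and 2.56, 2.67, 2.49, 1.61, 17.2, 17.55, 19.55, 24.55, 29.47 and 21.86 in the remission group. Active replicate 2 and remission replicates 1 to 4 were thus the 5 shallow libraries, with under 5 M, and 1 count per M gene counts (CPM) stood, before TMM scaling, for between 1.61 and 31.75 reads.

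The active libraries stood apart from all others in how their reads mapped. Reads set aside for low mapping quality came to 1.20 per gene count in active libraries (SD 0.17, n = 12), against 0.668 (SD 0.0297, n = 10) in healthy and 0.681 (SD 0.045, n = 10) in remission libraries. The ranges did not overlap, and both differences had a permutation p of 1e-05, the smallest that 100000 permutations can give (adjusted p = 5e-05 over 24 tests). Processed pseudogenes, copies of messenger RNAs scattered through the genome, held 12.5% of the gene counts in active, 7.85% in healthy and 8.33% in remission libraries. Ribosomal protein genes held 2.85%, 1.65% and 1.73%, also without overlap between the active group and the others. Genes detected at equal depth were fewest in active (mean 19092), then in remission (19430) and healthy (19988) libraries. Both disease groups differed from healthy (permutation adjusted p = 0.00029 and 0.00288), with overlapping ranges. At full depth active libraries had 22138 detected genes on average (20139 to 24858) and healthy libraries 28421 (27661 to 29105), without overlap. Their mean gene counts were 22.2 M and 22.5 M. The labels name no batch, and a batch that coincides with the active group cannot be told apart from active disease. Every gene difference of the active group below therefore carries this limit.

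**Figure D1:**
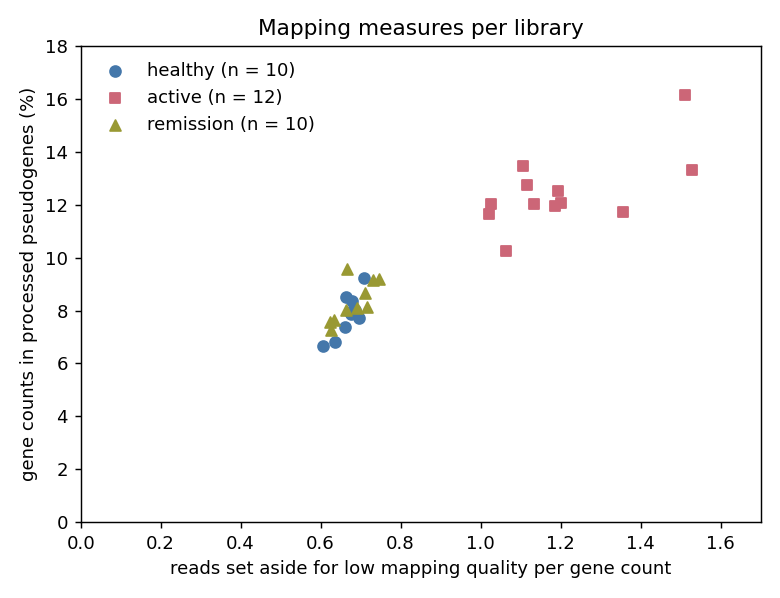
Reads set aside for low mapping quality per gene count (x axis) against the percentage of gene counts in processed pseudogenes (y axis), 1 point per library. The 12 active libraries lie between 1.021 and 1.528 on the x axis, and the healthy libraries between 0.606 and 0.709.

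**Figure D2:**
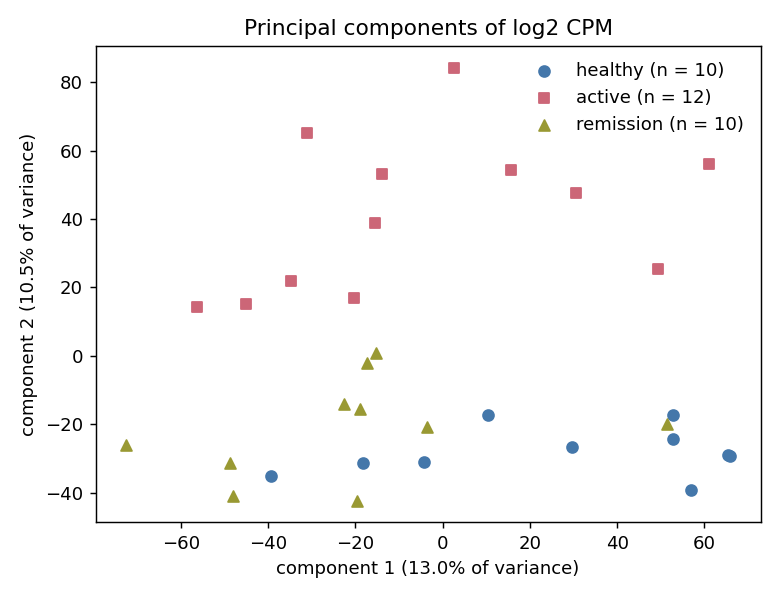
First and second principal components of log2 CPM of the tested genes, which hold 13% and 10.5% of the variance, 1 point per library. The 12 active libraries lie above the other 20 on the second component.

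The comparison of active JIA with healthy controls asks how CD4+ T cells differ in children whose arthritis was active despite treatment. All 28 ribosomal protein genes of the fixed list rose, by a median log2 fold change of 0.91. Among them RPS24 went from 188 to 439 CPM (log2 fold change 1.22, SE 0.10), RPS20 from 292 to 697 and RPS14 from 262 to 599, each higher in 12 of 12 active libraries than in every healthy one. Of 30 nuclear genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, 27 rose and 3 did not pass, with a median of 0.65. COX7C, a subunit of cytochrome oxidase, rose by 1.22 (SE 0.10), and NDUFS5 and NDUFB9, subunits of complex I, by 1.22 (SE 0.11) and 0.98 (SE 0.09). MALAT1 (ENSG00000251562.3), an abundant nuclear long noncoding RNA, rose from 2357 (SD 634) to 9846 (SD 1489) CPM, a log2 fold change of 2.06 (SE 0.13, edgeR adjusted p = 9.54e-14), in 12 of 12 active libraries above every healthy one.

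Among genes of T cell identity and signalling, CD3D, a chain of the T cell receptor complex, rose from 138 to 273 CPM (log2 fold change 0.98, SE 0.08, edgeR adjusted p = 5.24e-12, all 12 active libraries above every healthy one). The list of T cell receptor signalling moved both ways: CD3D, CD3E (0.33) and the kinase LCK (0.25) rose, while 5 fell, among them NFATC2 (-0.42), LAT (-0.38), the kinase ZAP70 (-0.32) and NFATC1 (-0.24), and 11 of 19 members did not pass. Adjusted over the list alone, 3 rose and 5 fell as well, and the list did not pass (camera adjusted p = 0.757, upward, with a median of -0.03 and a mean of -0.01). The Th1 list, genes of interferon gamma producing helper cells, had 6 members that fell and 1 that rose among 14, with the same counts adjusted over the list alone. RUNX3, a transcription factor of cytotoxic and Th1 cells, fell by 0.68 (SE 0.10), in 12 of 12 active libraries below every healthy one. EOMES, another factor of cytotoxic and Th1 cells, fell from 20.2 to 10.2 CPM (SE of the log2 fold change 0.21). TBX21, which encodes the Th1 factor T-bet, fell by 0.93 (SE 0.26), and IL18RAP, a subunit of the interleukin 18 receptor, by 1.27 (SE 0.34). HAVCR2 and CXCR3 fell by 0.76 and 0.53, and LTA, which encodes lymphotoxin alpha, rose by 0.56. The list as a whole did not pass (camera adjusted p = 0.116).

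The regulatory T cell list fell as a whole (camera adjusted p = 0.0151, median log2 fold change -0.36, adjusted p = 0.603 with an estimated correlation), and its mean was below the healthy median in 12 of 12 active libraries. Its 5 members that fell, of 16 and also of 16 adjusted over the list alone, were IL2RB (-0.85), a chain of the interleukin 2 receptor shared with NK and effector cells, TNFRSF18 (-0.67) and TNFRSF1B (-0.56), receptors that activated T cells also carry, IKZF2 (-0.49), which encodes Helios, and the interleukin 10 receptor gene IL10RA (-0.34). IKZF2 lost its call in 11 of 19 other settings. FOXP3, the defining factor of regulatory T cells, did not pass (31.6 CPM in healthy and 26.4 in active libraries, -0.26, SE 0.16), nor did IL2RA (-0.21). Beside both lists, 4 of 14 markers of NK and cytotoxic cells fell: FCRL6 (-1.46), GNLY (-1.33), SPON2 (-1.04) and PRF1 (-0.96), which encodes perforin, with 5 adjusted over the list alone. That list did not pass (camera adjusted p = 0.0689, adjusted p = 0.868 with an estimated correlation), nor did its mean (difference -0.95, permutation adjusted p = 0.0836, below the healthy median in 11 of 12). With the NK marker mean as a covariate 5 of the 11 fallen genes of the Th1 and regulatory lists passed. The mean of the CD8 markers was 0.59 in active and 1.51 in healthy libraries on the log2 CPM scale (difference -0.92, adjusted p = 0.0294 by a permutation test, below the healthy median in 12 of 12). The neutrophil marker mean was 0.02 against 1.37 (difference -1.35, permutation adjusted p = 0.0263, below the healthy median in 12 of 12). Only 6 of 14 listed neutrophil markers had enough counts to be tested, and 0 of them passed. Of 6 CD8 markers 1 fell. Neither list passed by camera (adjusted p = 0.173 for neutrophil and 0.363 for CD8 markers). The CD8 difference did not pass without the 5 shallow libraries (-0.85, permutation adjusted p = 0.0601), and with the median over each list neither CD8 (-0.76) nor neutrophil markers (-0.92) passed (permutation adjusted p = 0.125 for both).

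In the list of interferon gamma response and antigen presentation, 5 of 18 members rose and 2 fell, or 5 and 3 adjusted over the list alone. B2M, the invariant chain of HLA class I, rose by 0.94 (SE 0.09) from 5996 to 11500 CPM. The immunoproteasome subunits PSMB10, PSMB9 and PSMB8 rose by 0.68, 0.62 and 0.49, and IRF1 rose by 0.51 (SE 0.18), a call lost in 6 of 19 other settings. CIITA, the regulator of HLA class II genes that B cells and monocytes also express, fell by 1.19 (SE 0.41), and TAPBP by 0.20. The list passed as a whole (camera adjusted p = 0.03, adjusted p = 0.706 with an estimated correlation). Of 25 genes of the type I interferon response, ISG15 (1.17, SE 0.32), IFI6 (0.74) and LY6E (0.48) rose, 2 of them also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.267). The call of IFI6 was lost in 10 of 19 other settings, and with low-mapping-quality reads as a covariate ISG15 (-0.97), IFI6 (-1.09) and LY6E (-0.35) changed sign without passing.

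Of 15 genes of the TGF-beta and SMAD pathway 7 fell, or 9 adjusted over the list alone (camera adjusted p = 0.0444, adjusted p = 0.603 with an estimated correlation). They included TGFB1 (-0.59, SE 0.12), which encodes the cytokine itself, the receptor gene TGFBR3 (-0.79, SE 0.17) and SMAD3 (-0.38, SE 0.08). After offsets for exon length, GC content and exon size 2 of the 15 fell and 1 rose. Of 30 chromatin modifiers 16 fell, also adjusted over the list alone, such as TET3 (-0.44), ARID1A (-0.41) and EP300 (-0.36). After these offsets 0 of the 30 passed as lower and 3 as higher. The offsets also shifted the folds of all genes by a median of 0.061. With them TET3 was at -0.19, ARID1A at -0.12 and EP300 at -0.15. The chromatin list had a camera adjusted p of 0.0151 (adjusted p = 0.706 with an estimated correlation). Among genes near JIA risk loci 7 of 28 fell, such as TYK2 (-0.43) and SH2B3 (-0.60), and TIMMDC1 (0.36) and IRF1 rose, against 11 and 2 adjusted over the list alone (camera adjusted p = 0.247).

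Among transcripts that track RNA handling, 3 of 15 mitochondrial transcripts rose: MT-ND3 (1.11), MT-CO3 (0.76) and MT-CO2 (0.59), with a camera adjusted p of 0.0297 (adjusted p = 0.868 with an estimated correlation). Of 7 other noncoding and nuclear RNAs in a list of their own, MALAT1, KCNQ1OT1 (1.40) and GAS5 (0.45) rose (camera adjusted p = 0.0253, adjusted p = 0.387 with an estimated correlation). Both counts were also 3 adjusted over the list alone. The ribosomal and oxidative phosphorylation lists had camera adjusted p values of 2.19e-38 and 7.75e-24, and 0.0289 each with an estimated correlation; their list means were higher in 12 of 12 active libraries than in every healthy one. Of the large genes that fell, PLEC went from 1533 to 826 CPM (-0.89, SE 0.12) and FLNA, which encodes the actin crosslinker filamin A, from 1459 to 922 CPM (-0.66, SE 0.08), and with offsets for exon length, GC content and exon size they were at -0.41 and -0.29.

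**Figure D3:**
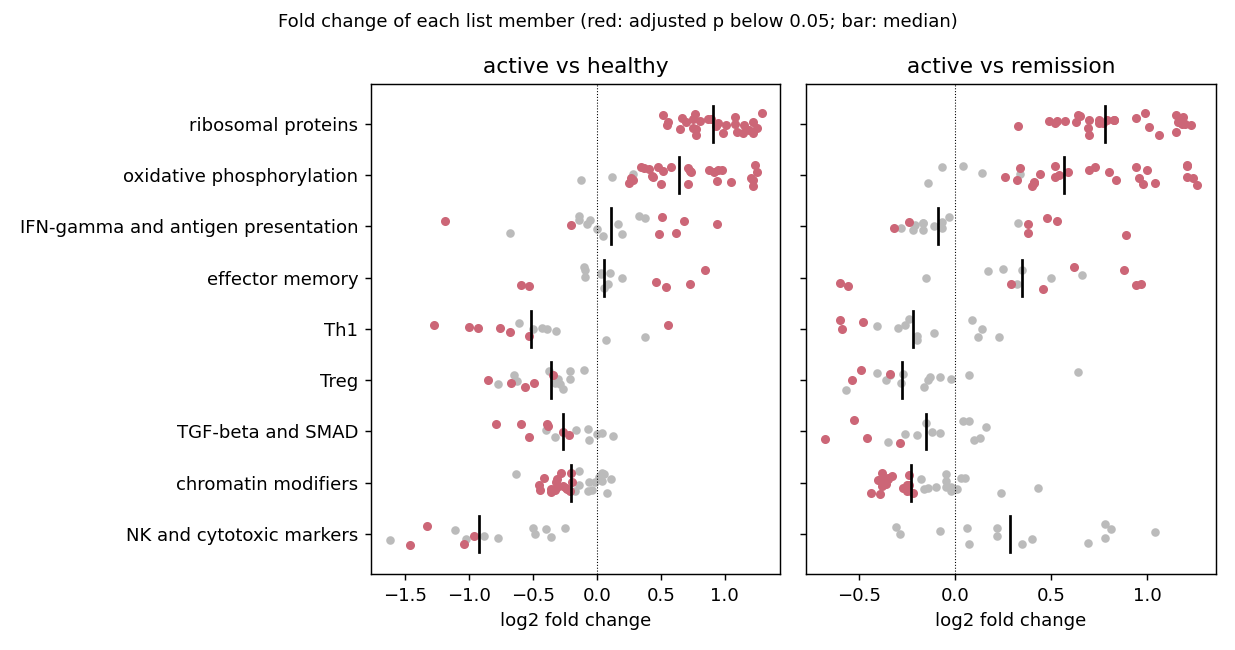
Log2 fold change of each member of 9 lists in active against healthy libraries (left) and active against remission libraries (right), with red points for an adjusted p under 0.05 and a bar at the median. All 28 ribosomal protein genes lie above 0 in both. With offsets for exon length, GC content and exon size the count of chromatin modifiers that passed as lower against healthy went from 16 to 0.

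In total 4764 of 19798 genes passed between active and healthy libraries (edgeR, adjusted p under 0.05), 2626 higher and 2138 lower, and 1795 of them changed by 1.5-fold or more. Without the 5 shallow libraries 4704 passed. The split moved with the scaling: 1986 higher and 3646 lower with library size alone, which shifted the median of all genes by -0.095. With surrogate variables it was 2905 and 5019. With offsets for exon length, GC content and exon size it was 3104 and 748, and the folds shifted by a median of 0.061. Among processed pseudogenes 610 of 2171 were higher and 47 lower, and among protein-coding genes 1680 of 13282 were higher and 1878 lower. With low-mapping-quality reads per gene count as a covariate 306 genes passed, 229 of them among the 4764 in the same direction, such as CD3D, MALAT1, COX7C and RPS24, and 1 in the opposite direction. This covariate does not overlap between active and other libraries, so a kept call does not show that a difference is free of the mapping difference. Nor does a lost call show that a difference went away: RUNX3 (-0.65), EOMES (-1.52), TGFB1 (-0.86), IL2RB (-0.61) and B2M (0.57) did not pass with this covariate. Other genes lost the call with smaller folds left, such as PSMB10 (0.21), PSMB8 (0.11), LCK (0.07) and IL10RA (-0.11). With the offsets ZAP70 (-0.07), IL10RA (-0.10), SKI (-0.10), TYK2 (-0.13), SMAD3 (-0.17), NFATC2 (-0.24), LAT (-0.30), IKZF2 (-0.32), MT-CO2 (0.36) and TNFRSF18 (-0.47) no longer passed, nor did GNLY (-1.26), CIITA (-0.95) and IFI6 (0.66), and TAPBP and NFATC1 turned to 0.01 and 0.06. Of 19 other settings, GNLY lost its call in 10, CIITA in 9 and CXCR3 and LAT in 6 each. TAPBP and NFATC1 lost theirs in 8 each and changed sign in 2 more.

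**Figure D4:**
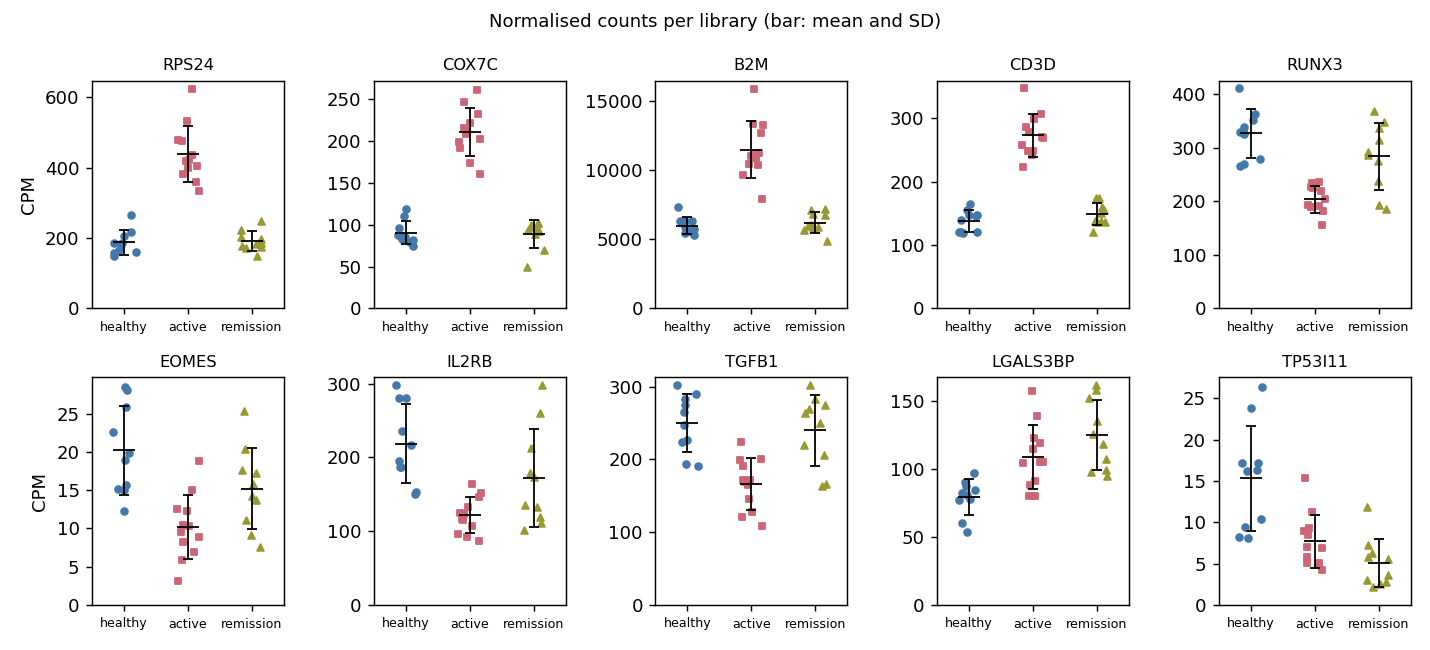
Normalised counts (CPM) of 10 genes named in the text, 1 point per library, with the group mean and SD. RPS24, COX7C, B2M and CD3D are higher and RUNX3 is lower in every active library than in every healthy one, while LGALS3BP and TP53I11 passed between remission and healthy.

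The comparison of active JIA with remission on medication asks what sets active disease apart when both groups were treated. Ribosomal protein genes again rose, 28 of 28 with a median of 0.78, such as RPS20 (1.20, SE 0.10) and RPS24 (1.20, SE 0.10). Of the oxidative phosphorylation genes 25 of 30 rose, with COX7C at 1.24 (SE 0.10), and adjusted over the list alone 26 rose and 1 fell. MALAT1 rose from 2107 (SD 337) to 9846 (SD 1489) CPM (2.22, SE 0.13, edgeR adjusted p = 1.04e-14, 12 of 12 active libraries above every remission library). Both B2M (0.89, SE 0.09) and CD3D (0.88) rose as well.

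The effector memory list was higher as a whole in active than in remission libraries (camera adjusted p = 0.0103, median 0.36, adjusted p = 0.898 with an estimated correlation). Its mean was 6.18 in healthy, 6.28 in active and 5.95 in remission libraries. Between remission and healthy it passed as lower (camera adjusted p = 0.000213), though not with an estimated correlation (adjusted p = 0.195). Of its 15 members 6 rose and 2 fell, or 8 and 2 adjusted over the list alone. The monocyte and dendritic marker means were also higher in active libraries (differences 1.22 and 0.90, in 10 and 11 of 12 above the remission median), without passing (permutation adjusted p = 0.204 and 0.0803), and against healthy the list did not pass (camera adjusted p = 0.315). With the monocyte and neutrophil covariate it passed against remission (camera adjusted p = 0.0144, median 0.23). S100A4, a calcium-binding protein of memory cells and monocytes, rose by 0.94 (SE 0.16) and KLRB1, which encodes CD161, by 0.88 (SE 0.23), while CXCR3 fell by 0.60 and AHNAK by 0.56. KLF2, a factor that keeps T cells quiescent and recirculating, fell by 0.71 (SE 0.13), from 826 to 506 CPM. Of the JAK-STAT genes 8 of 23 fell, among them TYK2 (-0.38), IL6R (-0.36), STAT3 (-0.27) and STAT5B (-0.26), and IL2RG (0.20), the common gamma chain, rose, or 9 and 1 adjusted over the list alone. That list did not pass (camera adjusted p = 0.061). PDCD1, the checkpoint receptor PD-1, fell by 0.60 (SE 0.18).

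Of 30 chromatin modifiers 16 fell, or 17 adjusted over the list alone, among them ARID1A (-0.44) and HDAC4 (-0.38), and 8 fell after offsets for exon length, GC content and exon size (camera adjusted p = 0.00123, adjusted p = 0.601 with an estimated correlation). POLR2A, the large subunit of RNA polymerase II, fell by 0.67 (SE 0.08), the fatty acid synthase gene FASN by 0.69 (SE 0.09), and PLEC from 1648 to 826 CPM, and with the offsets FASN was at -0.36 and PLEC at -0.58. Of 12 histone genes whose messages mostly lack a poly(A) tail 9 rose, also adjusted over the list alone, such as H1-4 (2.00, SE 0.40) and H1-3 (1.73, SE 0.37). Their list passed with a camera adjusted p of 0.00438 (adjusted p = 0.601 with an estimated correlation), and its mean was 2.44 in active and 1.55 in remission libraries (permutation adjusted p = 0.00684, above the remission median in 11 of 12). The healthy mean of 2.07 lay between them. Of 7 noncoding and nuclear RNAs MALAT1, KCNQ1OT1 (1.32), GAS5 (0.35) and SNHG1 (0.32) rose, the last with its call lost in 12 of 18 other settings, and 5 rose adjusted over the list alone (camera adjusted p = 0.0115, adjusted p = 0.268 with an estimated correlation). Among B cell markers TCL1A (1.91, SE 0.65) and CD79B (0.67, SE 0.17) were higher than in remission and 12 of 14 did not pass. TCL1A was at 14.01 CPM in healthy, 8.85 in active and 2.69 in remission libraries. The B cell list did not pass (camera adjusted p = 0.0586, adjusted p = 0.898 with an estimated correlation), nor did its mean (difference 0.63, permutation adjusted p = 0.146, above the remission median in 10 of 12). FCER1A of the dendritic list was higher than in remission by 2.02 (SE 0.66). The B cell mean was 3.09 in healthy, 2.43 in active and 1.79 in remission libraries, and the dendritic mean 2.95, 2.5 and 1.6. Both active means thus lay below healthy, without passing (permutation adjusted p = 0.204 and 0.388).

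In total 4287 genes passed (edgeR), 2344 higher and 1943 lower in active libraries, with 1481 at 1.5-fold or more and 3651 passing without the 5 shallow libraries. With library size alone 1860 were higher and 3141 lower, with surrogate variables 2538 and 3486, and with offsets for exon length, GC content and exon size 1940 and 1154. The ribosomal and oxidative phosphorylation lists had camera adjusted p values of 1.51e-39 and 2.23e-23, and 0.0252 each with an estimated correlation. With low-mapping-quality reads per gene count as a covariate 360 genes passed, 261 of them among the 4287, including MALAT1, RPS20, CD3D and KLF2; this covariate does not overlap between the groups either. With the offsets IL2RG (0.08), STAT5B (-0.13), STAT3 (-0.17) and IL10RA (-0.19) no longer passed, nor did TCL1A (1.80), FCER1A (1.84), PDCD1 (-0.51) and SNHG1 (0.28), at folds nearer to those without offsets. Without the 5 shallow libraries AHNAK (-0.37), PDCD1 (-0.43), TCL1A (2.26) and IL2RG (0.16) no longer passed. Of 19 other settings TCL1A lost its call in 9, FCER1A in 7 and PDCD1 and IL2RG in 6 each, and IL2RG changed sign in 1 more.

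The comparison of remission on medication with healthy controls asks what remains different once the disease is quiet. LGALS3BP (ENSG00000108679.8), a secreted glycoprotein that binds galectins, rose from 78.9 (SD 13.3) to 125 (SD 25.7) CPM (log2 fold change 0.67, SE 0.12) and was higher in 10 of 10 remission libraries than the healthy median. CD72, a surface receptor mainly of B cells, fell from 6.65 to 2.59 CPM (-1.36, SE 0.25), and TP53I11 fell from 15.3 to 5.07 CPM (-1.61, SE 0.29), each below the healthy median in 10 of 10 libraries. ST6GALNAC1, an enzyme that adds sialic acid to glycans, was at 9.89 CPM in healthy and 25.1 CPM in remission libraries and did not pass (1.34, SE 0.26, edgeR adjusted p = 0.0515). The immediate-early genes NR4A1 (46.2, SD 77.9, and 1.88 CPM) and EGR1 (73, SD 115, and 6.84 CPM), which respond within minutes to stimulation, did not pass by edgeR either (-4.99, SE 1.12, and -3.51, SE 1.01), though both passed by DESeq2. Their healthy levels varied widely between libraries, and over the other settings the folds ran from -5.33 to -1.14 and from -3.59 to -0.12.

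Markers of other blood cells were at lower levels in remission libraries, without passing gene by gene. Among the B cell markers MS4A1, which encodes CD20, was at 38.6 CPM in healthy and 7.13 CPM in remission libraries (-2.70, SE 0.68, edgeR adjusted p = 0.335), and 9 of 14 members were lower adjusted over the list alone. Of the NK and cytotoxic markers 10 of 14 were lower adjusted over the list alone, such as FCRL6 (12 and 4.36 CPM) and SPON2 (33.9 and 18 CPM), and 10 of 20 immediate-early genes were lower and 1 higher. Over all genes 0 members of each of these lists passed. The monocyte marker mean was 4.66 (SD 2.00) in healthy and 2.54 (SD 1.75) in remission libraries on the log2 CPM scale (difference -2.12, permutation adjusted p = 0.07, below the healthy median in 9 of 10). The B cell, dendritic and NK marker means differed by -1.29, -1.35 and -1.19, each with a permutation adjusted p of 0.07.

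**Figure D5:**
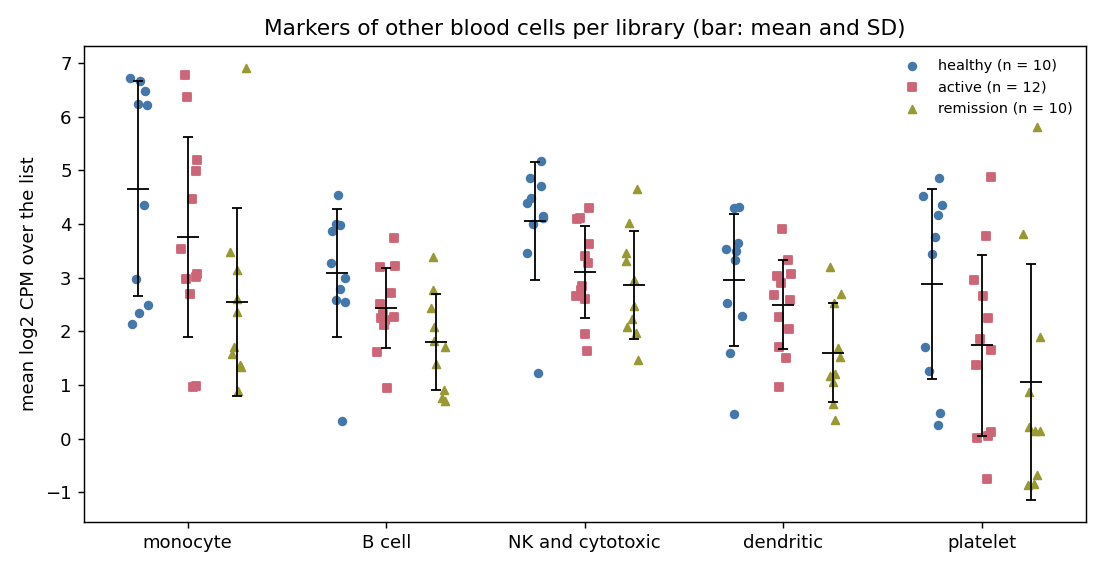
Mean log2 CPM of the markers of 5 other blood cell types, 1 point per library, with the group mean and SD as bars. The monocyte mean runs from 0.88 to 6.92 in remission and from 2.13 to 6.71 in healthy libraries.

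In all 3 genes passed (edgeR, adjusted p = 0.0279 each) and 1258 had an unadjusted p under 0.05, while DESeq2 called 30 and voom 32. By camera 22 of 38 lists passed, 17 lower and 5 higher, the latter being naive and central memory, T cell receptor signalling, type I interferon, interferon gamma and JAK-STAT. None of the 22 passed with an estimated correlation (lowest adjusted p = 0.174 with an estimated correlation), and fry called 0. Without the 5 shallow libraries 0 genes passed by edgeR. Over the other settings, this one included, the folds ran from 0.54 to 0.75 for LGALS3BP. They ran from -1.38 to -1.02 for CD72 and from -1.74 to -1.12 for TP53I11. Leaving out 1 library gave 0 genes without healthy replicate 1, 2, 4, 7 or 9 or without remission replicate 1, 2, 7, 8, 9 or 10, 1 gene without remission replicate 4 or 5, 5 without active replicate 1, 7 or 12, and 12 without healthy replicate 10.

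Across the 3 groups 4853 genes differed (edgeR test of any difference). Of the genes that passed in active JIA against healthy and against remission, 3371 were shared, 2018 higher and 1353 lower in both, with 0 in opposite directions. Independence would give 311 and 210, and with the active libraries divided into separate sets for the comparisons a mean of 1875 genes was shared (range 1743 to 1996 over 10 divisions). LGALS3BP and TP53I11 were the 2 genes that passed in both disease groups against healthy, higher and lower in both. Independence would give 0.133 and 0.216 genes. With the healthy libraries divided into 2 sets of 5 a mean of 0.4 was shared, and the range of 0 to 4 includes the 2 observed. Simulated unchanged groups had 0 calls in either comparison, so their overlap of 0 was fixed and cannot serve as a measure. The covariance of the log2 fold changes was 0.0864, against 0.0628 in simulated groups that shared the healthy libraries. The correlation was 0.42 against 0.50 in the simulated groups. Those simulations gave every group the same spread, while the real active libraries varied more than the healthy ones. With the healthy libraries divided, so that the comparisons shared none, the mean covariance was still 0.046 and the mean correlation 0.20.

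Libraries of the active group also differed more among themselves. The median within-group SD of log2 CPM over genes was 0.476 in active, 0.355 in remission and 0.272 in healthy libraries. A library's mean deviation from its group was 0.255 larger in active than in healthy (0.553 against 0.298, permutation adjusted p = 3e-05) and 0.159 larger than in remission libraries (permutation adjusted p = 0.00195). At a mean CPM of 10 or more the differences were 0.063 and 0.036, and after thinning to the smallest library 0.054 and 0.049. Remission exceeded healthy by 0.097 (permutation adjusted p = 0.0282), by 0.027 at a mean CPM of 10 or more, by 0.005 after thinning and by -0.009 without the 5 shallow libraries.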

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

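Chosen only after the results were seen were the tests on processed pseudogenes, on a batch, on the shallow remission libraries and on the gene property trend in the Th1 and regulatory T cell lists, as well as the spreads given for the short-exon, shallow-library, monocyte and NK tests. The shallow-library and monocyte spreads resampled libraries, with the outermost draws left out, and the NK spread resampled genes. In 94 groups of libraries 7 single values stood far from the rest of their group, where chance gives about 5%. The limit used is that for groups of 10, so the flags do not speak for the 12 active libraries. Among those, replicate 2 had 34.1% of its reads not aligned, against an active median of 9.25%. The B cell marker mean of healthy replicate 10 was 0.32 (other healthy libraries 2.54 to 4.54), and its NK marker mean was 1.22 (others 3.46 to 5.18). Remission replicate 6 had a monocyte marker mean of 6.92 (others 0.88 to 3.48) and an interferon gamma and antigen presentation mean of 7.74 (others 6.58 to 7.10). Remission replicate 9 had a ribosomal protein mean of 7.21 (others 7.77 to 8.37) and an oxidative phosphorylation mean of 4.61 (others 4.88 to 5.11). The CD8 marker mean of remission replicate 1 was -1.35 (others 0.32 to 2.09). Outside the gene counts, reads set aside for low mapping quality came to 1.20 per gene count on average in active libraries, above the healthy range of 0.606 to 0.709.

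The first pattern is that ribosomal protein, oxidative phosphorylation and many other genes differed between active libraries and both other groups. Several technical causes fell short as the whole cause, with the values for healthy and then remission as the comparison: with offsets for exon length and GC content 60.1% and 60.2% of the genes were called again in the same direction, with exon size added 59.9% and 59.8%, with the monocyte and neutrophil covariate 89.9% and 87.1%, with thinning to the smallest library 62.9% and 63%, and 21.6% and 18.7% of coding genes with no processed pseudogene named after them passed. For oxidative phosphorylation 9 of the 11 members without such a pseudogene rose in both comparisons, while 0 ribosomal protein genes of the list lack one, so reads shared with pseudogenes stay open for those. For a different yield of unspliced alignments at short exons, fold change correlated with mean exon size across coding genes at -0.043 and -0.068. Both lay above the bound that this cause was set in advance to fall under. The test still leaves this cause open: the first lies within its spread of the bound of -0.05 set in advance for ruling it out, and the second below that bound. With exon length the correlations were -0.311 and -0.303, and with GC content -0.136 and -0.155. A library or sequencing batch cannot be told apart from active disease: 0 active libraries lay within the range of the others in low-mapping-quality reads per gene count in either comparison, so a batch may account for much of the pattern, and active disease itself is an untested explanation. Chance is argued against for the active group, as 1 of 60 splits, the real one, reached 4764 genes against healthy (highest other 422). The same held for 4287 genes against remission (highest other 1267) and 4853 for any difference (highest other 2). Between remission and healthy the real split gave 3 genes (highest other 1), a gap too small to exclude chance. Leaving out 1 library gave 0 genes there in 11 of 32 fits.

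The second pattern is that markers of monocytes, B cells, NK cells and dendritic cells had lower means in remission than in healthy libraries, as had neutrophil markers (-1.12), although none of these differences passed (permutation adjusted p = 0.07 each, below the healthy median in at least 9 of 10 libraries for the first 4). Shallow remission libraries as the whole cause are argued against: with the 6 deep remission libraries the mean difference over the 4 lists was 117.5% (bootstrap SD 18) of that with all 10, at -1.75 against -1.49. Carry-over of monocytes alone stays open, since with the monocyte mean as a covariate the B cell and NK difference was -0.80 against -1.24, or 64.4% (SD 43.2), a spread too wide to decide. A purer selection of CD4+ cells in the remission libraries, whose method the labels leave unclear, is a candidate explanation, as is a change of the blood with disease or treatment, and neither was tested.

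The third pattern is that 11 genes of the Th1 and regulatory T cell lists, among them RUNX3, EOMES, TBX21 and IL2RB, were lower in active than in healthy libraries. The Th1 list mean was 4.88 in healthy, 4.44 in active and 4.64 in remission libraries, and the regulatory one 5.23, 4.73 and 4.96. Between active and remission neither list passed (camera adjusted p = 0.816 and 0.301), with 3 members of each lower in active. Between remission and healthy both passed as lower (camera adjusted p = 0.000625 and 0.000545), though not with an estimated correlation (adjusted p = 0.174 each). A trend with exon length, GC content and exon size is argued against as the whole cause, since 8 of the 11 still passed as lower with the offsets (median -0.53 against -0.68). Fewer NK and cytotoxic cells may account for part of it: with the NK mean as a covariate the median was -0.48, or 70.4% of its size. That lay between the bounds set in advance, and 5 of the 11 passed. The SD of the percentage, 8.6, came from resampling the 11 genes rather than the libraries, so it leaves out the spread between libraries. A batch that coincides with the active group cannot be told apart from active disease for these genes either, since 0 active libraries lay within the range of the others in low-mapping-quality reads per gene count. A change of CD4+ T cell states with active disease was not tested, and FOXP3, IL2RA and the Th1 list as a whole did not pass.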

How the results depend on the processing

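The offsets for gene properties, the low-mapping-quality, NK and monocyte covariates, the coding genes without processed pseudogenes and the fits without the 5 shallow libraries were chosen after seeing the data. For 144 named gene values 2364 of 2696 values under other settings kept the direction and side of the threshold, 285 lost the call, 27 gained it and 20 reversed. Counts outside 1.5 times the reported one follow, and the cause was not tested except where fewer genes or a fold limit explain it. Between active and healthy 8050 genes passed without a filter, 7924 with surrogate variables, 306 with the low-mapping-quality covariate, 2509 among coding genes without processed pseudogenes and 1795 at 1.5-fold or more. Between active and remission the last 3 gave 360, 2172 and 1481. For any difference the 5 gave 8298, 7352, 195, 2609 and 1988. Between remission and healthy edgeR called 0 without a filter, with surrogate variables, without the 5 shallow libraries and with the monocyte and neutrophil, monocyte, NK or sex-linked transcript covariates, 5 without robust fitting and 6 with only the 2 groups, while DESeq2 called 30 and voom 32. Leaving out 1 library gave 4204 to 4936 genes for active against healthy, 0 to 12 for remission against healthy, 3663 to 4582 for active against remission and 4476 to 5229 for any difference. Lists passing went from 8 to 2 with an estimated correlation and 14 by fry (active against healthy), from 22 to 0, 0, 14 with surrogate variables and 12 with the monocyte and neutrophil covariate (remission against healthy), and from 6 to 2, 12 and 12 without the 5 shallow libraries (active against remission). The overlap of the disease groups was 5 genes at an adjusted p of 0.10 and 0.4 with split healthy libraries. The spread of remission over healthy was 0.027 at a mean CPM of 10 or more, 0.005 after thinning and -0.009 without the 5 shallow libraries, and 2 marker tests passed without these, against 4. The noncoding and nuclear RNA mean of active against remission was among those lost (0.48, permutation adjusted p = 0.101).

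With the low-mapping-quality covariate, signs reversed against healthy for SMAD3 (0.07), EP300 (0.10), ISG15 (-0.97), LY6E (-0.35), IFI6 (-1.09), CD27 (-0.16), CRIP1 (-0.13), AHNAK (0.32), NFATC2 (0.10) and IL2RA (0.10), and against remission for AHNAK (0.33), EP300 (0.10), NFATC2 (0.07), ISG15 (-1.22), CD79B (-0.31) and IL2RG (-0.04). With offsets for length and GC content they reversed for TAPBP (0.03) and NFATC1 (0.07), and with exon size added for TAPBP (0.01) and NFATC1 (0.06). The cause was not tested. Depth limits genes of low level: 1 CPM was 1.61 reads in the shallowest library.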

Other observations

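Glycolysis and hypoxia genes moved both ways between active and healthy libraries: 6 of 20 rose and 1 fell, also adjusted over the list alone. LDHA, which makes lactate, rose from 136 to 192 CPM (log2 fold change 0.50, SE 0.11) and TPI1 from 69.1 to 103 CPM (0.57, SE 0.11). The list did not pass (camera adjusted p = 0.201, upward, with a median of -0.02 and a mean of -0.05). Of 16 naive and central memory genes 3 rose, among them the costimulatory receptor gene CD27 (0.48), and KLF2 (-0.41) fell. GATA3, the Th2 factor, fell by 0.39 (SE 0.10), and the survival gene BCL2A1 rose by 0.95 (SE 0.13).

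Stress and immediate-early genes spread widely among healthy libraries. HSPA1B, an inducible heat-shock protein, was at 146 CPM (SD 326, n = 10) in healthy, 15.9 CPM (SD 11.4, n = 12) in active and 12 CPM (SD 4.2, n = 10) in remission libraries. It passed between active and healthy (-3.21, SE 0.74), although only 7 of 12 active libraries lay below the healthy median and the call was lost in 5 of 19 other settings. The immediate-early mean ran from 4.05 to 7.26 in healthy, 3.60 to 5.92 in active and 3.64 to 5.32 in remission libraries on the log2 CPM scale.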
